A study of Homo sapiens with 12 samples.

How the data were processed

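RNA from 12 sorted human cell samples was amplified, labelled with biotin and hybridized to Illumina HT-12 v4 bead arrays, per the labels. The deposited raw table holds 1 linear intensity per probe and array, which the authors left without normalization and without background subtraction, and it has no column of detection p-values. The deposited normalized table holds log2 values, and the authors do not state the method. From the values, it is the log2 of the raw signal minus the log2 of the array's 75th percentile, less 1 constant per probe. That constant was taken separately over the 6 KO and WT arrays, as their median, and over the 6 HET arrays, where it is not the median of those arrays. Levels in that table therefore do not compare between the KO or WT arrays and the HET arrays. The column medians of that table ran from -0.140 to 0.0396, and the series matrix held the same log2 values as deposited (largest difference 0).

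Values were computed from the raw signals, because these were not centred separately for the KO and WT arrays and the HET arrays. This does not remove other differences between those 2 sets of arrays. Background was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, followed by quantile normalization and log2. Detection p-values were planned for the filter and were not used here, so the fallback fixed with the plan was applied: a probe was kept if it lay above the median of all probes on at least 2 arrays. Of 47323 probes, 30113 had 1 gene symbol in the annotation used, 8 had several and 17202 had none. Of several probes of a gene the one with the highest mean over all arrays was taken, which left 15279 genes, 4282 of them with more than 1 retained probe. Gene identifiers of 15261 were found in the RefSeq gene table, and 0 symbols differed. On the normalized scale the array median is 6.14, the 25th percentile 5.95 and the 99th percentile 11.9, so a group level near 6 is at the dim end and a fold against it can be understated. NR2F2, KCNJ3, TNNT2 and some HOX genes, which had no probe under their name, were not analysed here.

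Samples were grouped by title. For HET CT replicate 1 and HET RA G-/M+ replicate 1 the treatment entry opposes the title, and the design text numbers the G-/M+ samples differently from the titles. Titles were used: Pearson r across genes was 0.990 between the 2 HET CT arrays and 0.994 between the 2 G-/M+ arrays, against 0.971 for HET CT replicate 1 with HET RA replicate 1. The 2 G-/M+ arrays and the 2 HET arrays of each arm are called replicates in the labels, which do not say whether they were independent differentiations. KO replicate numbers are lines.

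RA against CT cardiomyocytes (5 against 5) and the comparisons of genotypes over both arms were fitted with limma on the 10 cardiomyocyte arrays with genotype and arm as terms. Comparisons within a genotype or an arm, G-/M+ against G+/M+ cells and the interaction were fitted on all 12 arrays with 1 mean per group, so all 7 groups shared 1 estimate of spread and a lone array was assumed to vary like the others. Tests were two-sided, with Benjamini-Hochberg adjustment over 15279 genes and a threshold of 0.05, and "passed" or "called" means under it. Differences are log2, first group minus second, with the standard error of the fit, and a level is a group's mean with its SD.

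The 25 gene lists were tested in 11 comparisons with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over 275 tests. A list is called by camera at the preset correlation, and 0 calls in any comparison held with an estimated correlation. Fry's p asks whether a list's genes move on balance 1 way and its mixed p whether they change in either direction, and neither compares the list with other genes. Counts "adjusted over the list alone" used the list's own members as the family. Named genes were chosen by rule: past the threshold and moving the same way in every opposing pair of arrays, the 12 largest rises and 12 largest falls for RA against CT, 10 and 10 for KO against HET and for G-/M+ cells, and 5 and 5 elsewhere, the most changed members of each list, and a short set of cardiac markers always. XIST, TSIX and genes of the Y chromosome were left out of these picks, so a largest rise or fall is among the other genes. List members that moved against their list, and genes in the last part of the closing section, were named after their values were seen.

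Whether numbers pair arrays was checked by the correlation across genes of deviations from group means, which was 0.218 between the KO arms, 0.083 between the HET arms and 0.272 between HET RA cardiomyocytes and G-/M+ cells. Across genotypes it was 0.054 between the KO and HET CT arrays and 0.165 between the KO and HET RA arrays. With the number as a block, 2877 genes passed for RA against CT cardiomyocytes, 2053 in HET, 1521 in KO, 175 for the interaction, 3261, 2789 and 4609 for KO against HET in RA, in CT and over both, and 5146 for G-/M+ cells. For KO against HET the block crossed genotypes and joined equal numbers, although KO numbers are lines and HET numbers are replicates.

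The fits were tested on simulated data with 100 genes changed by 0.5 and 100 by 1 (log2). All changes of 1 were recovered except for KO against WT (94%), and changes of 0.5 were recovered in 97% for RA against CT, 62% within HET, 72% within KO, 64% for KO against HET in RA, 44% for KO against WT and 56% for G-/M+ cells. False calls were 0% to 8.02% of calls. Noise was drawn independently for each array, without spread between lines. For KO against WT the simulated HET arrays kept their RA effect and the others had none, which adds to the spread of that fit.

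The alternatives, fixed with groups, tests, gene lists and the rule for named genes before the data were examined, were other normalizations, the authors' normalized table within each array set, other filters and probe choices, other priors and array weights, a fold threshold, blocks, subsets of arrays and leaving out each array. Added after the data were seen were a shift by upper quartile without centring, fits within each array set, KO against WT in the RA arm, and WT in place of HET in the interaction. The authors' table was not used for comparisons that cross its sets, and a chip block was not run because the columns name no chip. Figures were drawn with matplotlib 3.10.9.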

Results

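Genome-wide expression was measured on 12 Illumina HT-12 v4 bead arrays in cells differentiated for 3 weeks, as spin embryoid bodies, from human embryonic stem cells with an eGFP reporter in NKX2-5 and, except in wild type, an mCherry reporter in COUP-TFII (NR2F2). COUP-TFII is a nuclear receptor of atrial cells, and NKX2-5 is an early cardiac transcription factor. RA marks cells given 1 uM retinoic acid from day 4 to day 7, and CT marks the other arm, which the labels do not spell out. Cells were sorted on eGFP (G) and mCherry (M), and the series design calls RA G+/M+ cells atrial cardiomyocytes and CT G+/M- cells ventricular cardiomyocytes. The 4 knockout (KO, mCherry/-) arrays came from 2 lines, each with 1 RA and 1 CT array. Wild type (WT) had 1 RA and 1 CT array, sorted on eGFP alone. The heterozygous reporter (HET, mCherry/+) had 2 RA and 2 CT cardiomyocyte arrays and 2 RA arrays of G-/M+ cells that were not cardiomyocytes.

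Raw probe signals had array medians from 97.8 to 112.2 and minima from 73 to 82.1, and the number of arrays, 12, limits the precision. The 99th percentile of raw signal was 3190.9 to 3576.6 on the 6 KO and WT arrays and 4106.3 to 4934.7 on the 6 HET arrays, so the arrays fell into 2 sets that follow genotype. After normalization, replicate arrays of a group had Pearson r from 0.990 to 0.994 across genes, which are not independent replicates. COUP-TFII itself was not analysed here, because no probe carried its name in the annotation used, so loss of the targeted transcript was not followed.

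The first comparison set RA against CT cardiomyocytes, 5 arrays against 5, and asked what separates the cells the design calls atrial from those it calls ventricular. Genes of ventricular identity fell in RA cardiomyocytes: IRX4, a ventricular transcription factor, fell by 3.88 ± 0.22 (log2 ± SE, adjusted p = 1.19e-07), from a mean of 11.04 ± 0.35 (SD, n = 5) to 7.16 ± 0.53. MYH7, the slow myosin heavy chain, fell 10.3-fold, HEY2, a transcriptional repressor of the compact ventricular wall, fell 7.82-fold, and MYL2, the ventricular regulatory light chain, fell 6.07-fold (adjusted p = 0.00115). NR2F1, the closest relative of COUP-TFII, rose from 6.09 ± 0.19 to 9.05 ± 0.16 (log2 difference 2.96 ± 0.09, adjusted p = 1.39e-09), and KCNA5, the channel of the atrial ultrarapid potassium current, rose 2.19-fold (adjusted p = 6.73e-05). With limma, 2906 of 15279 genes passed, 1607 higher and 1299 lower in RA.

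The largest rises, each in every opposing pair of arrays within a genotype, were in SPOCK1 (9.9-fold, log2 3.31 ± 0.17), which encodes a matrix proteoglycan, NR2F1, the complement gene C7 (7.74-fold), the fatty acid binding protein FABP5 (6.84-fold) and ISL1 (6.65-fold), a transcription factor of cardiac progenitors and pacemaker cells. MYH11, smooth muscle myosin, rose 6.43-fold, ALDH1A1, an enzyme that makes retinoic acid, 6.26-fold, and MYBPHL, a myosin binding protein of atrial muscle, 5.15-fold. NELL1 (5.49-fold), PTCHD1 (5.34-fold), MGARP (5.01-fold) and the WNT receptor FZD7 (4.76-fold) completed the 12 largest rises. Among the 12 largest falls, beside IRX4, MYH7, HEY2 and MYL2, were COL22A1 (7.3-fold), GADL1 (5.81-fold), the long noncoding RNA VHRT (5.29-fold), PLCXD3 (4.67-fold), KCTD12 (4.59-fold), NAV1 (4.42-fold), the laminin chain LAMA4 (4.33-fold) and TNFRSF19 (4.23-fold). RA levels of MYL2, GADL1, VHRT and HEY2, and the CT level of NR2F1, lay between 6.04 and 6.37, near the array median of 6.14, so these folds can be understated.

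Of 19 ventricular genes measured, 14 fell and 1, the troponin gene TNNI3, rose (14 and 1 adjusted over the list alone). The list shifted down with camera (median log2 change -0.87, adjusted p = 2.60e-10, adjusted p = 0.211 with an estimated correlation). HAND1, a heart transcription factor, fell by 2.06 ± 0.24 within it. Of 19 atrial genes, 8 rose and 2, ROR2 and DKK3, fell (9 and 2 adjusted over the list alone), and the list shifted up (median 0.24, adjusted p = 0.00109, adjusted p = 0.317 with an estimated correlation). VSNL1, a calcium sensor gene, rose 4.74-fold and SLN, the atrial calcium pump regulator sarcolipin, by 0.66 ± 0.14, whereas 2 common atrial markers did not pass: NPPA, atrial natriuretic peptide, differed by 0.24 ± 0.28 (adjusted p = 0.633) and MYL7, the atrial light chain, by -0.02 ± 0.08 (adjusted p = 0.912). Of 22 sarcomere genes, 9 fell and TNNI3 rose (10 and 1 adjusted over the list alone), with LDB3 (-0.89) and MYOZ2 (-0.85) among the falls beside MYH7. That list shifted down (median -0.21, adjusted p = 6.87e-04, adjusted p = 0.4999 with an estimated correlation).

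Genes of fibroblasts and extracellular matrix were higher in RA cardiomyocytes. Of 19 measured, 11 rose, among them the collagens COL3A1 (3.97-fold) and COL1A2 (3.06-fold), and none fell (11 and 1 adjusted over the list alone). The list shifted up (median 0.40, adjusted p = 1.05e-06, adjusted p = 0.211 with an estimated correlation). Endothelial markers were higher over the 3 genotypes together: 5 of 14 rose, including TEK (1.96-fold) and CDH5 (log2 0.84 ± 0.21), and none fell (6 and 0 adjusted over the list alone; median 0.22, adjusted p = 0.0234). Within HET alone none of the 14 passed (median 0.05, adjusted p = 0.925 by camera). The endothelial call was lost with an estimated correlation (adjusted p = 0.807) and with fry (adjusted p = 0.143), and the list's median was -0.03 over the genes above the array median on all 12 arrays. Smooth muscle genes went both ways, ACTA2 rising 2.1-fold and MYLK 2.54-fold among 4 that rose and 2 that fell of 11, without a call.

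Among 19 genes of the retinoic acid pathway, 4 rose and 3 fell, without a call for the list. ALDH1A1 and the binding protein CRABP2 (2.33-fold) were higher, and the receptor RXRG fell by 1.01 ± 0.14. Of 13 HOX genes, 2 rose, HOXA2 by 0.63 and HOXB4 by 0.39. Ion channel and calcium handling genes split into 6 that rose and 7 that fell of 27, with CACNA1C, the cardiac calcium channel, down by 0.94. Of 21 cardiac transcription factors, 2 rose and 7 fell. The sort marker NKX2-5 differed by -0.26 ± 0.07 (adjusted p = 0.0176), a call lost without either WT array (adjusted p = 0.0589) and without HET RA replicate 1 (adjusted p = 0.0520).

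**Figure D1:**
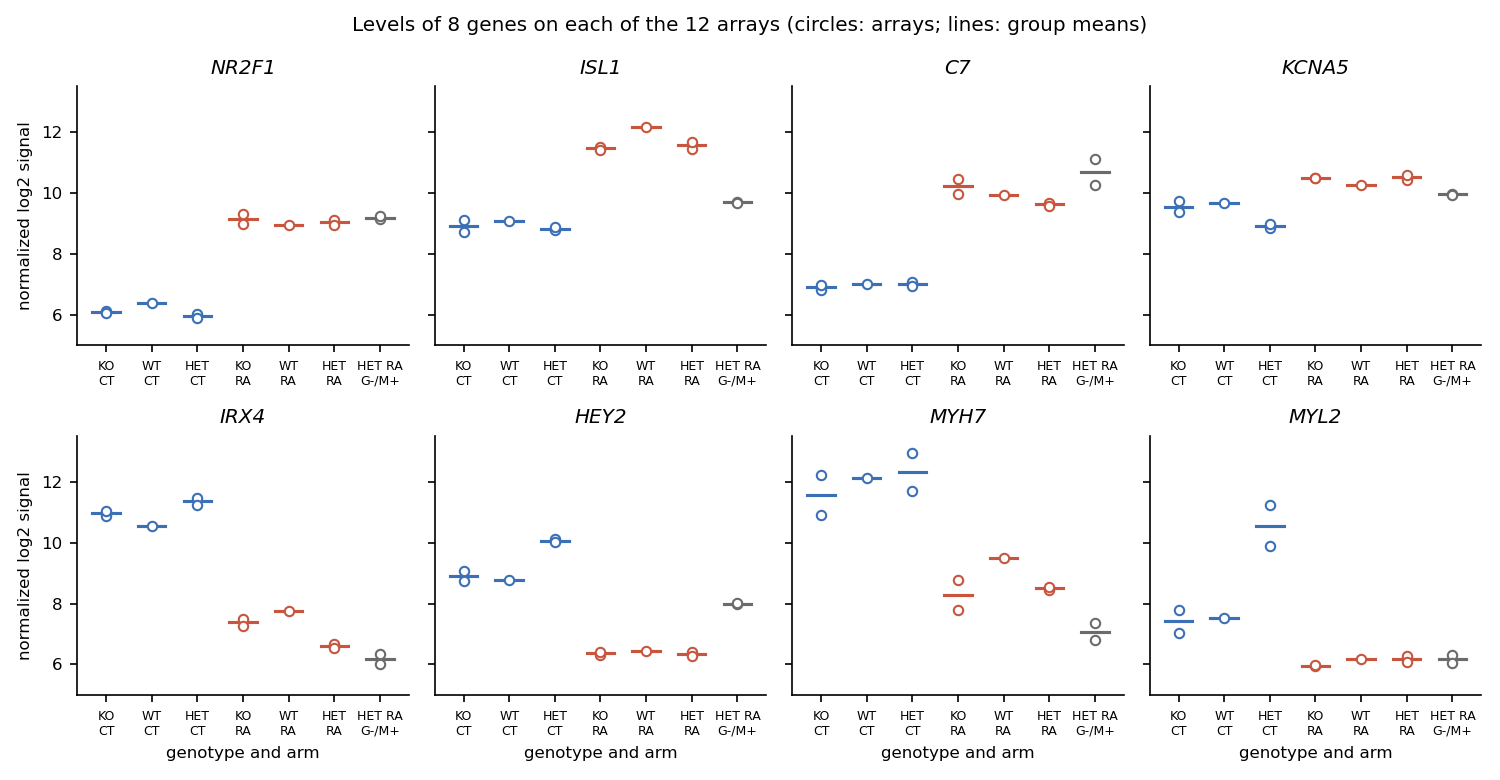
Normalized log2 signal (y axis) of 8 genes on each of the 12 arrays by genotype and arm (x axis), with circles for arrays and lines for group means. IRX4 means lie between 10.56 and 11.36 in the CT groups and between 6.19 and 7.77 in the RA groups, and NR2F1 means between 5.96 and 6.39 in CT and between 8.95 and 9.18 in RA.

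No list outside these passed camera in this comparison. Of the other lists, stress genes had 7 that rose and 3 that fell of 18, including FOS (log2 1.22) and CDKN1A (-1.20), FGF and WNT genes 5 and 8 of 22, with the WNT antagonists SFRP5 (1.59) and SFRP1 (1.26) higher, and BMP and TGF beta genes 5 and 3 of 16. Fatty acid oxidation genes had 7 that rose and 2 that fell of 18, glycolysis and hypoxia genes 2 and 4 of 18, NOTCH genes 2 and 3 of 12, with the ligand JAG1 up by 1.45, and epicardial genes 2 and 2 of 14. Sinoatrial genes had 1 and 1 of 11, neural genes 3 and 2 of 10, epithelial genes 1 and 3 of 10, skeletal muscle genes 1 and 1 of 7, hepatic genes 1 and 0 of 15 and cell cycle genes 1 and 0 of 23. Of 6 blood and 6 pluripotency genes, 0 passed with limma. Within the KO and WT arrays alone, 1915 genes passed (3 arrays against 3), and within the HET arrays alone 1481 passed (2 against 2), so RA and CT also differed inside each array set.

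The RA effect, meaning RA minus CT, was taken within each genotype to ask whether it held in HET, KO and WT cells. In HET and KO the RA cells were sorted as mCherry-positive and the CT cells as mCherry-negative, so there it joins treatment with the sort. WT was sorted on eGFP alone, so its RA minus CT is not the same quantity. In HET (2 arrays against 2), the log2 change was -4.74 ± 0.15 for IRX4, -4.38 for MYL2, -3.81 for MYH7 and -3.72 for HEY2, while SPOCK1 rose by 3.84, MYBPHL by 3.46, FABP5 by 3.34 and NR2F1 by 3.07. In KO (2 against 2), C7 rose by 3.32, MYH11 by 3.14, NR2F1 by 3.04 and ALDH1A1 by 2.87, while IRX4 (-3.57), MYH7 (-3.28) and COL22A1 (-2.71) fell. In WT (1 against 1), ISL1 rose by 3.09, MYH11 by 2.96, FABP5 by 2.94, C7 and SPOCK1 by 2.89, and NR2F1 by 2.56, and IRX4 fell by 2.79. NPPA rose by 1.18 in HET (adjusted p = 0.0463), a call lost without any 1 of the 4 arrays (adjusted p from 0.117 to 0.190), and its RA minus CT was -0.03 in KO and -1.08 in WT (adjusted p = 0.311). The difference in that effect between KO and HET, -1.21 ± 0.49, did not pass (adjusted p = 0.471).

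With limma, 1730 genes passed in HET (977 higher, 753 lower), 1299 in KO (721 and 578) and 649 in WT (377 and 272), where each arm was 1 array and was assumed to vary like the other groups. HET and KO shared 445 genes called higher (46.1 if the calls were independent) and 324 called lower (28.5 if independent), and 2 genes were called in opposite directions. The calls are not independent, because both comparisons use the same estimate of spread for each gene, so these expected counts can be too low. KO and WT shared 290 higher and 212 lower, with 0 opposite, and HET and WT 264 and 186, with 2 opposite. Ventricular genes fell in each genotype: 13 of 19 in HET (adjusted p = 4.10e-16, adjusted p = 0.0594 with an estimated correlation), 11 of 19 in KO (1.44e-09, adjusted p = 0.0779 with an estimated correlation) and 7 of 19 in WT (2.97e-09, adjusted p = 0.0779 with an estimated correlation). TNNI3 (0.76) and IRX5 (0.60) rose in KO. Adjusted over the list alone, 0 rose and 16 fell in HET, 2 and 13 in KO, and 2 and 11 in WT. Fibroblast and matrix genes rose in HET (6 rose and 1 fell of 19), KO (8 and 0) and WT (5 and 0), with adjusted p of 2.18e-04, 4.86e-07 and 9.93e-05, and adjusted p = 0.497, adjusted p = 0.323 and adjusted p = 0.466 with an estimated correlation. Atrial genes shifted up in HET (7 rose and 1 fell of 19, 9 and 2 adjusted over the list alone, adjusted p = 8.07e-04, adjusted p = 0.215 with an estimated correlation). They shifted up in KO too (5 and 0, 8 and 1 adjusted over the list alone, adjusted p = 5.41e-04, adjusted p = 0.212 with an estimated correlation). In WT 3 atrial genes rose and 2 fell (5 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.0807).

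Other lists moved in some genotypes. Endothelial genes shifted up in KO (4 of 14 rose, 7 adjusted over the list alone, adjusted p = 1.23e-04, adjusted p = 0.642 with an estimated correlation) and in WT (2 rose, 4 adjusted over the list alone, adjusted p = 0.00428, adjusted p = 0.787 with an estimated correlation). In HET none passed. Cell cycle genes shifted up in HET (5 of 23 rose, 10 adjusted over the list alone, adjusted p = 6.87e-04, adjusted p = 0.468 with an estimated correlation), while in KO 2 fell without a call (adjusted p = 0.0615). Sarcomere genes shifted down in KO (1 rose and 6 fell of 22, 1 and 8 adjusted over the list alone, adjusted p = 3.61e-04, adjusted p = 0.365 with an estimated correlation) and in WT (0 and 7, 1 and 9 adjusted over the list alone, adjusted p = 2.99e-06, adjusted p = 0.212 with an estimated correlation). In HET, cardiac transcription factors shifted down (1 rose and 6 fell of 21, 1 and 8 adjusted over the list alone, adjusted p = 0.0145, adjusted p = 0.299 with an estimated correlation). Smooth muscle genes shifted up in HET (6 rose and 2 fell of 11, 6 and 3 adjusted over the list alone, adjusted p = 0.0439, adjusted p = 0.803 with an estimated correlation).

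Camera called 6 of 25 lists in HET, 5 in KO and 4 in WT, and 0 with an estimated correlation. The HET count was 962 without RA replicate 1, 1074 without RA replicate 2 and 1152 without CT replicate 1. The KO count was 771 without RA line 1, 662 without CT line 1 and 665 without CT line 2.

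**Figure D2:**
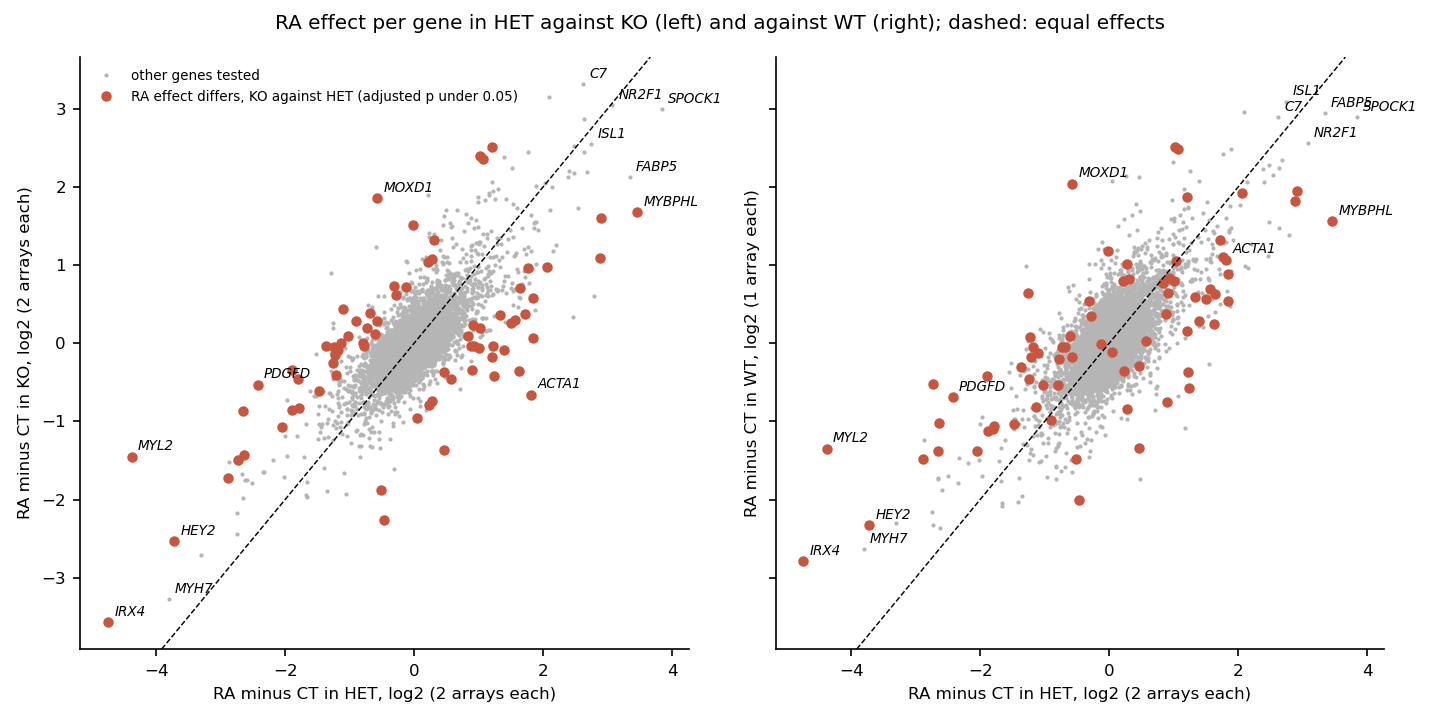
RA minus CT (log2) of each gene in HET cardiomyocytes on the x axis against KO (left) and WT (right) cardiomyocytes on the y axes, with genes whose RA effect differed between KO and HET in red. Across genes r was 0.71 for HET with KO and 0.65 for HET with WT, and IRX4 lies at -4.74 in HET, -3.57 in KO and -2.79 in WT.

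The interaction asked whether the RA effect in KO differed from that in HET, with a positive value where RA minus CT was higher in KO. The RA effect on several ventricular genes was less negative in KO: on MYL2 it was -4.38 in HET and -1.45 in KO, a difference of 2.93 ± 0.46 (adjusted p = 0.0162), IRX4 differed by 1.17 ± 0.19 (adjusted p = 0.0162) and HEY2 by 1.18 ± 0.17 (adjusted p = 0.00903). For MYL2 the difference lay in CT cells, at 10.56 ± 0.96 (SD, n = 2) in HET, 7.41 ± 0.52 in KO and 7.53 in WT, against 5.96 to 6.18 in all RA groups, and for HEY2 likewise (10.07 ± 0.05 in HET CT and 8.90 ± 0.25 in KO CT). Their RA levels were at the dim end, so the interaction there restates the lower CT level in KO. For IRX4, KO minus HET was 0.78 in RA (adjusted p = 0.00181) and -0.40 in CT (adjusted p = 0.0566). MOXD1 (2.43 ± 0.32), PDGFD (1.90 ± 0.27), S100A4 (1.78) and the transcription factor IRX3 (1.55 ± 0.23) had the other largest positive differences. ACTA1, skeletal alpha actin (-2.48 ± 0.39, adjusted p = 0.0151), the phospholipase gene PLCG2 (-1.98 ± 0.18, adjusted p = 4.33e-04), CAPN3 (-1.82), the muscle stress gene ANKRD1 (-1.80) and HHATL (-1.79) had the largest negative ones.

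With limma 74 genes passed, 41 higher and 33 lower, of 1375 with an unadjusted p under 0.05, and 48 of the 74 were also called in RA against CT cardiomyocytes. Of 19 ventricular genes, 5 had a higher RA effect in KO and none a lower one (7 adjusted over the list alone; median 0.50, adjusted p = 1.94e-08, adjusted p = 0.0779 with an estimated correlation). Of 21 cardiac transcription factors, 2 were higher (4 adjusted over the list alone; adjusted p = 0.00102, adjusted p = 0.211 with an estimated correlation). No cell cycle gene passed (7 of 23 lower adjusted over the list alone), and that list shifted down (median -0.30, adjusted p = 6.54e-10, adjusted p = 0.211 with an estimated correlation). Endothelial and epicardial lists shifted up without a member passing (4 and 0 of 14 adjusted over the list alone), and adjusted p was 0.564 and 0.706 with an estimated correlation. The RA effect in WT lay nearer to KO for 59 of the 74 genes and nearer to HET for 15, and with WT in place of HET 0 genes passed with limma (677 with an unadjusted p under 0.05, 4.43%). Of the 14 genes named by rule here, 11 lost their call without some single array, MYL2 with adjusted p from 0.0696 to 0.0799 and HEY2 with 0.0501. The count was 175 with the number in the title as a block, 28 without KO CT line 1, 36 without KO CT line 2, 23 without HET RA replicate 1 and 34 without HET RA replicate 2.

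KO against HET cardiomyocytes asked what differs with loss of COUP-TFII, with the KO arrays in 1 array set and the HET arrays in the other. CHCHD2, a mitochondrial protein gene, was the most different: its level was 10.46 ± 0.29 (SD, n = 4) in KO and 6.17 ± 0.22 in HET (log2 difference 4.29 ± 0.13, adjusted p = 1.67e-09), and it was 10.69 and 10.74 on the WT arrays. Transcripts of liver proteins were lower in KO than in HET: ALB, albumin, by 6.84-fold (log2 -2.77 ± 0.41), AFP, alpha-fetoprotein, by 6.08-fold, APOA2 by 5.12-fold and SERPINA1 by 4.01-fold. BHLHE40 (-2.54 ± 0.11), ITLN1 (-2.49), the interferon-induced MX1 (-2.36), ANKRD37 (-2.01 ± 0.07), the metallothionein MT1E (-1.98), whose probe can share sequence with its relatives, and COXFA4L2 (-1.81) were the other largest falls. WFIKKN1 (2.03), IRX3 (1.68), CACNG6 (1.67), BMP2 (1.59), PMEL (1.47), RBM38 (1.44), TUBB2B and SST (1.32) and FGFR3 (1.25) were higher in KO.

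With limma 4676 genes passed over both arms (4 arrays against 4), 2425 higher and 2251 lower in KO. The 4 KO arrays came from 2 lines, and the HET arrays carry 1 line name. The fit counts each array as independent, so its p-values do not measure spread between lines. The balance turned with scaling: 51.9% of calls were higher here, 45.8% with cyclic loess and 42.3% with a shift by upper quartile. Of 15 hepatic genes, 10 fell and none rose (10 adjusted over the list alone; adjusted p = 7.63e-05, adjusted p = 0.694 with an estimated correlation). Of 23 cell cycle genes, 17 fell, among them TYMS (-1.14) and TOP2A (adjusted p = 4.24e-04), and none rose (19 adjusted over the list alone; adjusted p = 1.99e-08, adjusted p = 0.564 with an estimated correlation). Of 18 glycolysis and hypoxia genes, 12 fell, including PFKFB3 (-1.64 ± 0.07), and 1, VEGFA, rose (12 and 1 adjusted over the list alone; adjusted p = 8.34e-06, adjusted p = 0.419 with an estimated correlation). AFP moved with these groups, at 10.98 and 10.84 in HET CT and RA cardiomyocytes and 11.55 in HET G-/M+ cells, against 8.26 and 8.36 in KO and 7.59 and 8.07 in WT. KO against HET and WT together gave 0 genes with limma (2946 with an unadjusted p under 0.05), a fit in which the difference between HET and WT counts as spread. MX1 lost its call without either KO CT array (adjusted p = 0.0548 and 0.0589). Its value also leans on HET CT replicate 1, without which KO minus HET in the CT arm was -1.42. MYL2 (-1.68, adjusted p = 0.0230) lost its call without KO CT line 1 (adjusted p = 0.0617), KO CT line 2 (0.0793) or HET CT replicate 2 (0.0592).

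In the RA arm alone, 3101 genes passed (1539 higher, 1562 lower): ACTA1 (-2.91) and MT1E (-2.64) were lower in KO, and IRX3 (2.46), WFIKKN1 (2.40), TUBB2B (2.08) and IRX4 (0.78) were higher. Of 23 cell cycle genes, 19 fell (19 adjusted over the list alone; adjusted p = 7.71e-13, adjusted p = 0.211 with an estimated correlation). Markers of other cell types moved in the same comparison: 6 of 14 endothelial genes rose (8 adjusted over the list alone; adjusted p = 5.41e-04, adjusted p = 0.694 with an estimated correlation). Of 15 hepatic genes, 8 fell (9 adjusted over the list alone; adjusted p = 9.48e-04, adjusted p = 0.797 with an estimated correlation). Of 18 glycolysis and hypoxia genes, 8 fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 1.23e-04, adjusted p = 0.642 with an estimated correlation). Of 21 cardiac transcription factors 7 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.0227, adjusted p = 0.323 with an estimated correlation). In the CT arm, 2635 genes passed (1419 higher, 1216 lower): MX1 (-3.46), MYL2 (-3.14 ± 0.33, adjusted p = 2.58e-04), APOA2 (-2.47) and HEY2 (-1.16) fell, and IRX2 (1.71), ACTN3 and RBM38 (1.49) and KCNA5 (0.64) were higher in KO. MX1 was -1.42 without HET CT replicate 1 (adjusted p = 0.0570) and also lost its call without KO CT line 1 (adjusted p = 0.105) or line 2 (adjusted p = 0.0885). KCNA5 lost its call without KO CT line 1 (adjusted p = 0.0551). Hepatic (9 of 15, 9 adjusted over the list alone), cell cycle (6 of 23, 9 adjusted over the list alone) and glycolysis and hypoxia genes (11 of 18, 12 adjusted over the list alone) fell in the CT arm too. Their adjusted p were 6.63e-05, 1.00e-04 and 2.29e-06, and adjusted p = 0.705, adjusted p = 0.419 and adjusted p = 0.4999 with an estimated correlation. In CT 53.9% of calls were higher in KO, but 46.5% with cyclic loess and 36.1% with a shift by upper quartile. In RA these shares were 49.6%, 44.5% and 37.7%. KO against HET and WT together gave 1368 genes in the RA arm. That fit kept HET and WT as separate groups, so their difference did not count as spread and the result includes KO minus HET. The RA count was 1892 without KO RA line 2, 1298 without HET RA replicate 1 and 1842 without HET RA replicate 2. The CT count was 995 without KO CT line 1, 1360 without KO CT line 2, 1654 without HET CT replicate 1 and 1639 without HET CT replicate 2.

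HET against WT, which also crossed the array sets, compared cells with 1 reporter allele and cells with none. The HET and WT cells also differed in line and in sort, so the effect of the allele cannot be told apart here. HET and WT each carry 1 line name, so the p-values measure spread between arrays, not between lines. AFP was higher in HET by 3.08 ± 0.48 (SE, 4 arrays against 2), ALB by 3.04, APOA2 by 2.69, ITLN1 by 2.42 and BHLHE40 by 2.41. CHCHD2 (-4.55 ± 0.16), the imprinted RNA H19 (-4.04 ± 0.88), CACNG6 (-1.84), IRX2 (-1.71) and WFIKKN1 (-1.63) were lower in HET. H19 lost its call without WT CT (adjusted p = 0.0504) or WT RA (0.0842), and ITLN1 likewise (0.0612 and 0.119). Of 15 hepatic genes, 10 rose (10 adjusted over the list alone; adjusted p = 1.24e-05, adjusted p = 0.642 with an estimated correlation). Of 18 glycolysis and hypoxia genes, 13 rose (13 adjusted over the list alone; adjusted p = 6.43e-11, adjusted p = 0.211 with an estimated correlation). Of 23 cell cycle genes, 11 rose (12 adjusted over the list alone; adjusted p = 2.31e-06, adjusted p = 0.694 with an estimated correlation), and 6 of 14 endothelial genes fell (8 adjusted over the list alone; adjusted p = 9.62e-04, adjusted p = 0.694 with an estimated correlation). In all, 3276 genes passed with limma, 1608 higher and 1668 lower in HET (49.1% higher, against 54.6% with cyclic loess and 62.6% with a shift by upper quartile), and the count was 1450 without WT CT and 1178 without WT RA.

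KO against WT, both in the same array set, asked for the effect of losing both copies (4 arrays against 2). The fit takes the same difference in both arms, so a difference in RA cells alone would be averaged with CT cells. The KO arrays came from 2 lines, and the WT arrays carry 1 line name. The fit counts each array as independent, so its standard errors and p-values measure spread between arrays, not between lines. In the CT arm KO cells were sorted as mCherry-negative, and WT cells of both arms were sorted on eGFP alone. No gene passed with limma (658 with an unadjusted p under 0.05, 4.31% of those tested; smallest adjusted p = 0.159). The differences were -0.06 ± 0.13 for NR2F1, 0.01 for IRX4, 0.03 for HEY2, -0.16 ± 0.62 for MYL2, 0.18 for NPPA and 0.06 for KCNA5. In simulated data, 44% of genes changed by 0.5 and 94% of those changed by 1 (log2) were recovered in this comparison. The simulated change was put in the KO arrays of both arms, and a change in RA alone was not simulated. The HET arrays kept their RA effect there while the KO and WT arrays had none, which the fit counts as spread. Noise was independent between arrays of a line, so these shares do not give the sensitivity of the real comparison. Glycolysis and hypoxia genes shifted up as a list (median 0.22, adjusted p = 1.57e-11, adjusted p = 0.211 with an estimated correlation), with 0 of 18 passing over all genes and 6 higher adjusted over the list alone. The endothelial list shifted down with 0 of 14 passing (adjusted p = 0.00116, adjusted p = 0.694 with an estimated correlation). In the RA arm alone 27 genes passed (1021 with an unadjusted p under 0.05). The count over both arms was 1 without KO CT line 2 and 2 without WT CT.

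**Figure D3:**
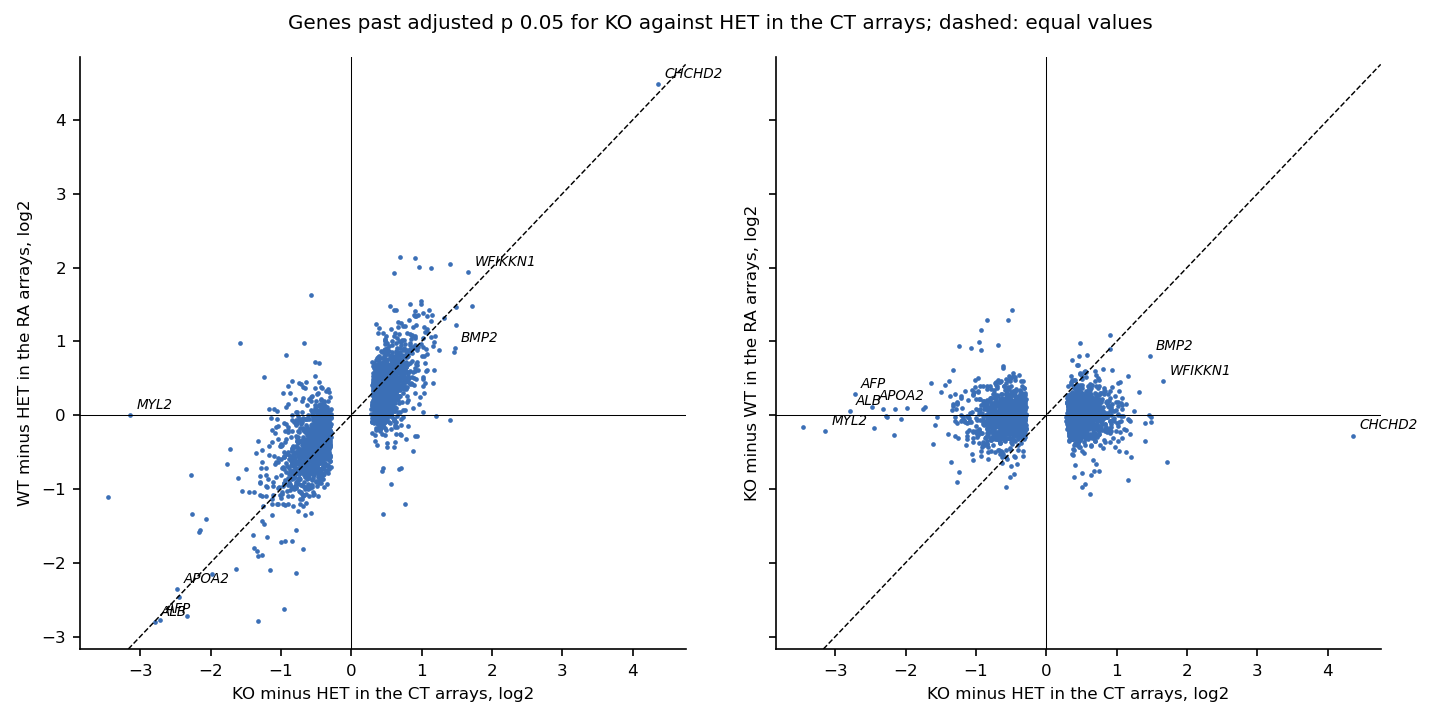
Each point is 1 of the 2635 genes called for KO against HET in the CT arm, with its KO minus HET log2 difference in CT on the x axis and, on the y axes, its WT minus HET (left) or KO minus WT (right) log2 difference in the RA arm. The slopes across genes are 0.76 and 0.01.

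G-/M+ cells against G+/M+ cardiomyocytes of the same HET line and treatment (2 arrays against 2) asked how cells with COUP-TFII but without NKX2-5 reporter differ. Stromal genes were higher in G-/M+ cells: BGN, biglycan, rose 13.3-fold (log2 3.73 ± 0.30), PDGFRB, a receptor of pericytes and fibroblasts, 11.4-fold (3.51 ± 0.23), DCN, decorin, 10.4-fold, and MGP 8.79-fold. GPR83 (9.56-fold), CA12 (9.45-fold), COLEC11 (9.11-fold), the sulfatase SULF1 (9.1-fold), the neuronal gene STMN2 (8.99-fold) and the transcription factor LHX2 (8.56-fold) were the other largest rises. The largest falls were in heart muscle genes: MYL3, a ventricular light chain, fell 36.8-fold (log2 -5.20 ± 0.15, adjusted p = 8.28e-10), HHATL 16.9-fold, CKM, muscle creatine kinase, 14.8-fold, NPPA 14.6-fold, troponin C TNNC1 12.6-fold, LDB3 10.2-fold and myoglobin MB 9.91-fold. NKX2-5, whose reporter was sorted on, fell 14.8-fold, and DDIT4L and HSPB7 fell 8.91-fold and 7.5-fold. NR2F1 differed by 0.15 ± 0.12 (adjusted p = 0.394), at 9.18 and 9.03.

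Of 19 fibroblast and matrix genes, 16 rose and 1, PDGFRA, fell (17 and 1 adjusted over the list alone; adjusted p = 1.08e-10, adjusted p = 0.211 with an estimated correlation), with LUM at 2.96 and COL6A3 at 2.91. Of 14 endothelial genes, 13 rose (13 adjusted over the list alone; adjusted p = 3.43e-08, adjusted p = 0.419 with an estimated correlation), including TEK (2.97), CDH5 (2.28) and CLDN5 (2.26). Of 14 epicardial genes, 9 rose (10 adjusted over the list alone; adjusted p = 5.24e-06, adjusted p = 0.466 with an estimated correlation), among them TCF21 (2.80). NOTCH genes rose in 9 of 12, including NOTCH1 (2.69) and HEYL (2.58), while the ligands JAG1 and JAG2 fell (9 and 2 adjusted over the list alone; adjusted p = 1.56e-04, adjusted p = 0.211 with an estimated correlation). Of 13 HOX genes, 8 rose, HOXB5 by 2.06 (8 adjusted over the list alone; adjusted p = 0.00183, adjusted p = 0.466 with an estimated correlation). Smooth muscle (6 of 11 rose, 6 and 1 adjusted over the list alone, adjusted p = 0.0335, adjusted p = 0.797 with an estimated correlation) and blood genes (4 of 6 rose, 4 adjusted over the list alone, adjusted p = 0.00974, adjusted p = 0.419 with an estimated correlation) also shifted up, with HBG2, whose probe can share sequence with HBG1, at 1.91 and CD34 at 1.87. Of 23 cell cycle genes, 13 rose, TOP2A by 1.06, and 1, AURKA, fell (13 and 1 adjusted over the list alone; adjusted p = 9.07e-05, adjusted p = 0.419 with an estimated correlation).

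Sarcomere genes fell in 19 of 22 (21 adjusted over the list alone; median -1.55, adjusted p = 4.10e-16, adjusted p = 0.0858 with an estimated correlation), TCAP by 2.85 and NEBL by 2.82. Fatty acid oxidation genes fell in 12 of 18 and rose in 1 (12 and 1 adjusted over the list alone; adjusted p = 1.24e-05, adjusted p = 0.330 with an estimated correlation), and PPARGC1A, a regulator of mitochondrial genes, fell by 2.72. Glycolysis and hypoxia genes fell in 12 of 18, PFKP by 2.05 (12 adjusted over the list alone; adjusted p = 2.29e-06, adjusted p = 0.4999 with an estimated correlation). Ion channel genes fell in 14 of 27 and rose in 3 (16 and 3 adjusted over the list alone; adjusted p = 7.35e-04, adjusted p = 0.211 with an estimated correlation), RYR2, the calcium release channel, by 2.34. Ventricular genes fell in 11 of 19 and rose in 4 (12 and 4 adjusted over the list alone; adjusted p = 0.00307, adjusted p = 0.212 with an estimated correlation), with HEY2 up by 1.65. Atrial genes fell in 9 of 19 and rose in 2, SLN by 2.44 among the rises (11 and 2 adjusted over the list alone; adjusted p = 0.0375, adjusted p = 0.452 with an estimated correlation). With limma 4790 genes passed, 2443 higher and 2347 lower, so that 51.0% were higher, against 57.7% with cyclic loess and 42.2% with a shift by upper quartile.

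**Figure D4:**
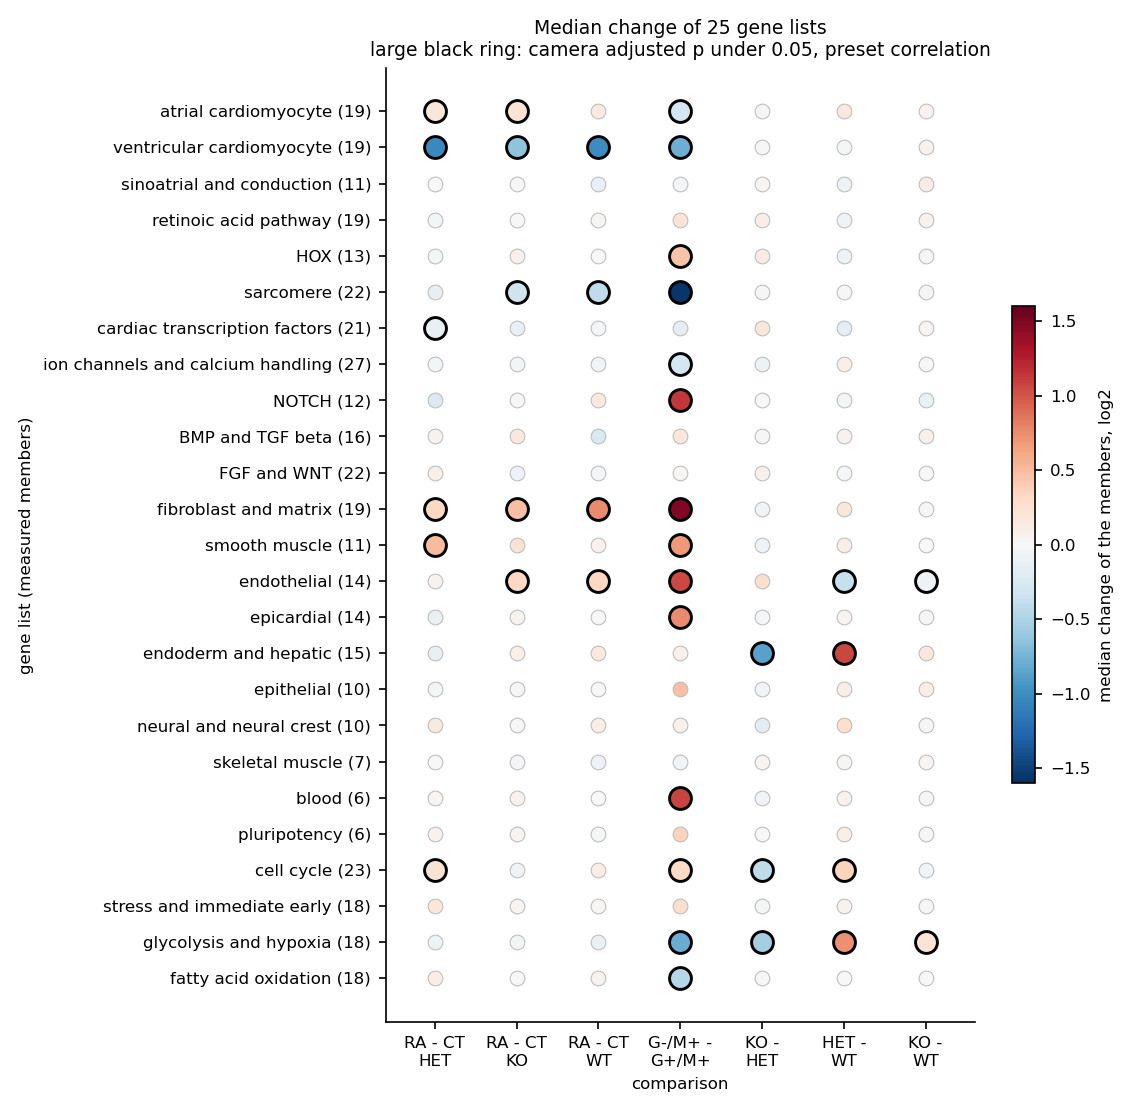
Median log2 change (colour scale) of the measured members of 25 gene lists (y axis) in 7 comparisons (x axis), with a black ring where camera gave an adjusted p under 0.05 with a preset correlation. The ventricular list has a median of -1.03 for RA minus CT in HET, and the sarcomere list has -1.55 for G-/M+ minus G+/M+ cells.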

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

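The tests of the array sets, of COUP-TFII copies and of G-/M+ cells, and the splits that follow the KO lines, were chosen after the results they concern were seen, whereas the other splits of the samples were planned.

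The RA effect differed between KO and HET at 74 genes by the interaction test. Among the genes named for RA against CT cardiomyocytes, the difference in log2 RA effect, KO minus HET, was 2.926 for MYL2, 1.1801 for HEY2, 1.1743 for IRX4, 1.1627 for NAV1, 0.80955 for SOX3 and -1.7841 for MYBPHL. KO minus HET for MYL2, HEY2 and SOX3 was -3.14, -1.16 and -0.95 in CT and -0.21, 0.02 and -0.14 in RA, where MYL2 and HEY2 were at the dim end, so their interaction restates the CT difference, whereas for IRX4, NAV1 and MYBPHL it was 0.78, 0.88 and -1.33 in RA. If copies of COUP-TFII made this difference, WT should lie on the side of HET. The RA effect in WT was nearer to KO for 79.73% of the 74 genes. That share rests on 1 WT array in each arm. WT cells were also not sorted on the COUP-TFII reporter, as HET and KO cells were, so the share leaves copies open. A property of the HET line, or of the arrays it was run on, may also account for the difference. These cannot be told apart because every HET array is in 1 set and every KO and WT array in the other.

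KO and HET cardiomyocytes differed at 4676 genes, and KO and WT at 0 over both arms with limma (658 with an unadjusted p under 0.05) and at 27 in the RA arm alone (1021). Among the 35 splits of the 8 KO and HET arrays into 4 and 4 only the real 1 gave as many genes and the highest other gave 0. The other splits leave the difference between KO and HET in the spread, which lowers their counts. The real split is also the split by array set, so it cannot tell genotype from set. Keeping the 2 arrays of each KO line together leaves 7 splits, too few for a share under 0.05, with 0 as the highest other. WT minus HET in the RA arm had the sign of KO minus HET for 91.954% of the genes called in the CT arm (91.9% with the arms exchanged), consistent with a property shared by the KO and WT arrays and absent from HET, which could be the array set or the cell line and cannot be told apart here. At genes picked on 1 KO and 1 HET array of the RA arm, KO minus WT on the other KO line followed KO minus HET with a slope of -0.011 to 0.034664 over the 4 choices of arrays, against 0.62 to 0.84 for KO minus HET on the arrays not used to pick, and an effect that grows with missing copies of COUP-TFII would need at least the latter. In the CT arm, where the KO and HET cells were sorted as negative for the COUP-TFII reporter, the slopes were -0.081 to -0.048 against 0.58 to 0.81. Each arm has 1 WT array, however, so an effect of copies in the RA arm stays open.

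Fibroblast and matrix genes were higher in RA than in CT cardiomyocytes. Cells of the G-/M+ kind among the sorted RA cardiomyocytes would bring all their abundant transcripts, but the 10 genes that set G-/M+ cells apart implied a median share of 2.5688% in the KO RA arrays (quartiles 0.97 and 2.85%), against 9.58% (quartiles 5.43 and 21.7%) implied by the 6 matrix genes that rose with RA in HET, with PDGFRB (2.87%) in both sets. Among the former APLNR implied 15.8%, COLEC11 5.90%, BGN 2.49% and DCN 0.93%, and among the latter COL6A3 4.55%, COL1A1 8.06%, COL1A2 11.1%, COL3A1 25.3% and PDGFRA 113%, more than all cells. The 10 genes were chosen as at least 8-fold lower in HET RA cardiomyocytes than in G-/M+ cells, and the 6 because they rose with RA in HET. Both choices widen the gap between the shares, so the gap cannot decide whether such cells account for the list. For PDGFRA alone, which was lower in G-/M+ than in G+/M+ cells, they cannot be the whole cause. This assumes that G-/M+ cells of the KO lines resemble those of HET. Expression by the cardiomyocytes themselves, or cells of another profile, may also account for the rise of the matrix genes, and neither was tested.

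For RA against CT cardiomyocytes, of 100 splits drawn from 126, only the real 1 gave as many genes as the 2906 observed, and the highest other gave 8. Among the 40 that part the 2 arrays of each KO line, the highest other gave 1. Other splits leave the RA difference in the spread, which lowers their counts. The splits also treat arrays of the same line as exchangeable, so they make chance unlikely for these arrays but do not exclude it over lines. Within the KO and WT arrays the 10 splits are too few for a share under 0.05; the real 1 gave 1915 genes and the highest other 0.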

How the results depend on the processing

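The fits within array sets, KO against WT in the RA arm, and WT in place of HET were chosen after the results were seen. Counts of genes stayed within 1.5 times the reported value under other normalizations, filters, probe choices, priors and weights, and the authors' table where used. Requiring a log2 change of at least 1 gave 216 genes for RA against CT cardiomyocytes, 284 in HET, 217 in KO, 245 in WT, 198, 124 and 123 for KO against HET in RA, in CT and over both, 140 for HET against WT and 940 for G-/M+ cells, fewer by construction. The number as a block gave 175 for the interaction. KO against HET and WT together gave 1368 in RA and 0 over both arms (2946 with an unadjusted p under 0.05), and these counts do not compare. The fit in RA kept HET and WT as separate groups, whereas the fit over both arms counted the difference between them as spread. RA against CT within the KO and WT arrays gave 1915 and within HET 1481, with fewer samples. KO against WT in RA alone gave 27; the cause was not tested. With WT in place of HET, 0 genes passed the interaction in limma (677 unadjusted), and CSRP3 (0.111), HEY2 (-0.20624), IRX4 (-0.78152), MOXD1 (-0.18389), MYL2 (-0.10462) and SOX3 (-0.22926) reversed. The endothelial list for RA against CT reversed to a median of -0.030359 over genes above the array median on all 12 arrays, which tests fewer genes, and RUNX1 in G-/M+ cells to -0.088327 without a filter; the cause was not tested. Leaving out each array gave 2370 to 2707 genes for RA against CT, 962 to 1426 in HET, 662 to 1077 in KO, 23 to 88 for the interaction, 1298 to 2391, 995 to 1654 and 3873 to 4452 for KO against HET in RA, CT and both, 1178 to 3243 for HET against WT, 0 to 2 for KO against WT and 3444 to 3809 for G-/M+ cells. The share higher moved with the upper quartile shift: 37.7% against 49.6% for KO against HET in RA, 36.1% against 53.9% in CT, 42.3% against 51.9% over both, 62.6% against 49.1% for HET against WT and 42.2% against 51.0% for G-/M+ cells, where cyclic loess gave 57.7%. Of 2852 values of named genes without 1 array, 2548 kept direction and call, 304 kept direction alone and 0 reversed; of 6218 under other settings, 5894, 317 and 7; of 489 for lists, 408, 80 and 1. Not run were the chip block and the authors' table across its sets. Signal over background limits genes near 6.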

Other observations

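H19, an imprinted growth-related RNA, was uneven among lines: its level was 9.18 and 9.95 on the CT and RA arrays of KO line 1, 9.56 and 10.4 on the WT arrays, and 5.94 and 5.95 on those of KO line 2, with 5.73 to 6.26 on the HET arrays. MX1, an interferon-induced gene, was uneven within HET CT cells, at 11.4 on replicate 1 and 7.36 on replicate 2. CHCHD2 was near the array median of 6.14 in every HET group, with means of 6.09 in CT cardiomyocytes, 6.26 in RA cardiomyocytes and 6.27 in G-/M+ cells, and lay between 10.2 and 10.7 on the KO and WT arrays.

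In the HET RA cells, ALDH1A2, an enzyme of retinoic acid synthesis, was higher in G-/M+ cells than in G+/M+ cardiomyocytes by 2.14 ± 0.39 (log2 ± SE, 2 arrays against 2). HOPX (2.05) and GJA1 (1.97) were also higher in G-/M+ cells, and ISL1 (-1.88) and BMP7 (-2.06) were lower.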
